A study of Mus musculus with 24 samples.

How the data were processed

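Pancreatic islets of male mice of the inbred strains C57BL6/J (BL6) and C57BLKs/J (BLKS) were measured on 24 single-colour Agilent arrays, 1 array per mouse. Mice entered at an age of 8 weeks and were fed chow with 18% of kcal from fat, a high-fat diet with 42% of kcal from fat, or the high-fat diet with pioglitazone at 140 mg per kg diet. Pioglitazone is an agonist of the nuclear receptor PPAR-gamma. The sample labels give 12 weeks of diet and the series design text gives 16 weeks, and the disagreement was left open. Each of the 6 groups held 4 mice, and groups were taken from the sample titles. Islets were taken from different animals in each group, so no mice were paired.

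Per the labels' protocols, islets were isolated after collagenase perfusion of the pancreas, and their total RNA was amplified and labelled with Cy3. Per the file headers, the arrays were read with Agilent Feature Extraction version 10.7.3.1, which gave each spot a background-subtracted and detrended intensity. That deposited intensity was not yet normalized between arrays. The raw spot intensity and the local background intensity, also deposited per the file headers, were used in 1 alternative. The authors' deposited value table held a linear ratio, which the values showed to be each array's processed intensity over that array's median, with the column median at 1. Of its columns of values, 0 were left unmapped to a sample.

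Each array carried 62976 spots, of which 59305 were not controls and made up 55681 distinct probes under 34797 gene names. Spots flagged as outliers were left out, which removed 55 probes, and no spot was flagged as saturated. The log2 processed intensity was averaged over the spots of a probe and expressed relative to the 75th percentile of its array. A probe was kept when it was well above background on at least 4 of the 24 arrays, which left 32750 probes. The brightest kept probe stood for each gene name, giving 22968 genes. Of these, 6653 had several kept probes. Among genes called between the strains on chow, 82.9% of the other probes had the same sign, so the probes of a gene could disagree. Gene names are those of the array design. Of the probes, 27235 (48.9%) were matched by accession to a current symbol in a table of the GRCm38.p6 assembly, and 2838 of those symbols differ from the file's name. Probe coordinates are those of the files, on mm9, and none were converted.

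A linear model with a mean for each of the 6 groups was fitted to all 24 arrays with limma 3.58.1 (lmFit and eBayes, in R 4.3.3 with data.table version 1.17.8). It gave 9 contrasts, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. All adjusted p-values for single genes are from this limma fit, and its errors are standard errors (SE) of the log2 difference. A gene not well above background on any array of a group has only a bound there. Its fold is then given as "at least", from the mean of the brighter group against the higher of the array's lowest well-detected signal and the probe's own signal.

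There were 28 gene lists with 705 entries, of which 692 had a probe. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 28 lists of a contrast. Camera with an estimated correlation and fry, which asks whether the members move together and does not compare them with other genes, were run beside it. The mean of a list's members on an array served as its score. Scores were compared by exact two-sided permutation tests over the 70 assignments of 8 arrays, whose smallest possible p is 0.0286.

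The genes named in each contrast followed a rule. It took the 8 highest and the 8 lowest log2 changes among genes past the threshold whose 4 arrays of one group all lay beyond the 4 of the other. Clone, predicted-gene and accession names were left out. Where fewer than 5 passed in a direction, the 5 lowest p-values of that direction were added as values that did not pass. Up to 4 members of smallest p were taken from lists called by camera or with at least 3 called members. Nnt, Ins1, Ins2, Gcg, Sst, Ppy, Pdx1, Mafa, Slc2a2, Atp2a2, Pparg and Mki67 were always taken. The groups, lists, tests, naming rule and most alternatives were set before the data were examined.

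The arrays lay on 4 slides. Slide 1 held the BL6 chow and high-fat groups. Slide 3 held the BLKS high-fat and pioglitazone groups. Slide 2 held 3 BL6 pioglitazone and 3 BLKS chow arrays, and the fourth array of each of these groups lay on slide 4, scanned on another day. The alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization alone, no filter, only probes well above background on all 24 arrays, the mean of a gene's probes, the authors' value table, slide as a random or fixed block, the mouse number as a block, only the groups compared, the acinar score as a covariate, and each mouse left out. Leaving out arrays of high lymphocyte score, that score as a covariate, and leaving out each mouse for the gene lists were added after seeing the data. The 5 arrays left out for that score were BL6 high-fat mouse 4, BL6 pioglitazone mice 2 and 3, BLKS high-fat mouse 3 and BLKS pioglitazone mouse 1. They scored more than 2 above the median of -2.64, which kept BL6 chow mouse 3 at -0.78 and, narrowly, BLKS chow mouse 2 at -0.65. No chow array was therefore left out, while BL6 pioglitazone mouse 2 at -0.48 was. Calls can be lost in that setting through fewer arrays alone.

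The procedure was tested on simulated data over 22968 genes. In the simulated comparison of high-fat diet with chow in BL6 islets, 32% of genes changed by 0.5 on the log2 scale, 62% of those changed by 1 and 94% of those changed by 2 were recovered, with 5 unchanged genes called. The simulation changed 50 genes at each size, a size of 3 included, and all cell cycle genes by 0.5. Its noise was drawn independently for each gene. Real contrasts with few changed genes or signals shared between genes can differ, so these shares are not their recovery or error rates. Between 49.16% and 58.28% of probes were well above background on an array. The number of arrays limits the precision of every value.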

Results

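Gene expression was measured in islets of 24 mice, 4 in each of 6 groups formed by 2 strains and 3 diets. BLKS mice share much of their genome with BL6 mice. The question named for the series is how the strains differ in their response to a high-fat diet. The 75th percentile of processed intensity ranged from 217.6 to 402.4 between arrays. The first principal component held 45.6% of the variance, and the next 2 held 21.5% and 5.5%. Array values of lymphocyte markers followed the second component (Pearson r = 0.97, Spearman rho = 0.93, permutation p = 1e-05, the smallest the resampling can give), and r was 0.95 without the 2 arrays farthest from the median. Acinar-cell markers followed component 3 (r = 0.95, rho = 0.92, permutation p = 1e-05), with r = 0.93 without the 2 farthest arrays. Within BL6 and within BLKS, r was 0.98 and 0.97 for lymphocyte markers and 0.91 and 0.99 for acinar markers. Only these 2 pairs of list and component were compared, and the list members are among the genes that define the components. The permutation p-values take no account of this, so the correlations only describe the components.

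Nnt, which encodes a mitochondrial transhydrogenase and is mutated in BL6 mice of the J substrain, served as a check of the strain labels. Its brightest probe (mm9 chromosome 13, 120124335 to 120124394) was 1.29 ± 0.07 (SE) higher on the log2 scale in the 12 BLKS arrays than in the 12 BL6 arrays (adjusted p = 8.4e-13), and the lowest BLKS array at 3.48 lay above the highest BL6 array at 2.71. A second probe was 2.99 higher and was well above background on 12 BLKS arrays and 0 BL6 arrays. Another, dim probe differed by 0.29. Whether these probes lie inside the deleted part was not determined here, so the check rests on the difference alone.

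High-fat diet against chow changed few genes in BL6 islets. Cdkn2c, an inhibitor of cyclin-dependent kinases (mm9 chromosome 4, 109333508 to 109333567), rose by 0.71 ± 0.10 (SE; adjusted p = 0.0058), from -0.69 ± 0.13 to 0.01 ± 0.06 (SD, n = 4). The immediate early transcription factor Egr1 fell by 1.76 ± 0.30 (adjusted p = 0.027), from 2.52 ± 0.66 to 0.76 ± 0.63. No isolation batch is given, so handling of the islets before lysis cannot be told apart from diet for this gene. NEAT2, an older name of the long noncoding RNA Malat1, fell by 1.32, and a probe under the name Malat1 that starts at the same position differed by -1.25 without passing (adjusted p = 0.065). A probe named for a transcribed region on chromosome 19 overlaps the NEAT2 probe and fell by 1.27 (adjusted p = 0.027), so this locus is counted more than once below. Lrtm2 fell by 0.91 and the carboxypeptidase gene Cpm by 0.63. The transcript A030001D16Rik, outside the naming rule and chosen after its values were seen, rose by 3.67 (adjusted p = 0.0026) and was well above background on 3 of the 4 chow arrays. With each of the 8 arrays left out in turn, Cdkn2c, Lrtm2 and A030001D16Rik still passed, while Egr1 did not in 5 of the 8 cases and NEAT2 and Cpm did not in 6. In all, 10 of 22968 genes passed, 4 higher and 6 lower (40% higher, and from 30% to 80% over other settings). Values that did not pass included Rasd2 at 1.27 (adjusted p = 0.051), Snai1 at 0.74, Npas4, an activity-regulated transcription factor, at 1.48 (adjusted p = 0.078), Tmem2 at 0.59, P2ry1 at 1.00, Jun at -1.39, Tac1 at -2.71 and Sytl2 at -1.15. The hormone genes Ins1, Ins2, Gcg, Sst and Ppy differed by 0.03, 0.07, -0.04, -0.10 and -0.43, none past the threshold. Pdx1, Mafa, Slc2a2, Atp2a2 and Pparg differed by between -0.27 and 0.09. With only these 8 arrays in the fit, limma called 0 genes (1623 at an unadjusted p under 0.05, against 1254 in the fit of all arrays). Without the arrays of high lymphocyte score the count was 5, with the acinar score as a covariate 6, and without high-fat mouse 1 it was 18.

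As a group, cell cycle and proliferation genes were higher on high-fat diet in BL6 islets, with a median log2 change of 0.68 over 40 measured members, 39 of them positive (camera adjusted p = 8.3e-11, and adjusted p = 0.73 with an estimated correlation). Their array score was 0.77 higher (exact permutation p = 0.0571). No single member passed over all genes, and 2 rose adjusted over the list alone. Its members of smallest p were Ccne1 at 0.63, E2f1 at 0.45, Prc1 at 0.96 and Aurka at 0.79, and Mki67 stood at 1.45 ± 0.82. Macrophage markers had a median of 0.64 over 23 members (adjusted p = 9.5e-08, and adjusted p = 0.73 with an estimated correlation), with Trem2 at 0.70, C1qb at 0.63 and Fcer1g at 0.46, and 1 member rose adjusted over the list alone. The array score of macrophage markers gave an exact permutation p of 0.0286 (0.2 adjusted over contrasts), and that of immediate early genes 0.2. The lymphocyte score was 0.47 higher on high-fat diet (exact permutation p = 0.743). Immediate early genes had a median of -0.20 over 22 members (adjusted p = 0.0015, and adjusted p = 0.73 with an estimated correlation), where 1 fell over all genes and 3 fell and 1 rose adjusted over the list alone, and Fos stood at -2.19, but the list did not pass without chow mouse 1 (median -0.15). Oxidative phosphorylation genes (median 0.07, adjusted p = 0.0062, and adjusted p = 0.76 with an estimated correlation) did not pass without chow mouse 2 or 4 or high-fat mouse 1 or 2, with medians from 0.03 to 0.11 over the 8 arrays left out in turn. Interferon response genes (0.16, adjusted p = 0.037, and adjusted p = 0.73 with an estimated correlation) did not without chow mouse 1 or 3 or high-fat mouse 1, 2 or 4 (medians from 0.03 to 0.26). Inflammation genes (0.27, adjusted p = 0.044, and adjusted p = 0.73 with an estimated correlation, with Ccl5 at 1.96 and Tnfaip3 at 1.15) did not without chow mouse 1, 2 or 3 or high-fat mouse 1 or 4 (medians from 0.18 to 0.42). The calls of these 3 lists also ended in 3, 5 and 7 of 12 other settings. Their array scores gave exact permutation p of 0.4, 0.429 and 0.0571 in this order. Acinar-cell markers, from exocrine tissue, had a median of 1.92 (adjusted p = 1.6e-05, and adjusted p = 0.73 with an estimated correlation), with Amy2a5 at 1.87 and Sycn at 2.58, while their array score differed by 1.71 (exact permutation p = 0.343). Without chow mouse 4 the acinar median was 0.54 and did not pass, and without chow mouse 2 it was 3.23.

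For high-fat diet against chow in BLKS islets, 18 genes passed, 4 higher and 14 lower. Of the lower ones, 6330545A04Rik was not well above background on any array of the 2 groups, so its call compares background signals. Arntl, a core activator of the circadian clock (mm9 chromosome 7, 120457261 to 120457320), fell by 0.92 ± 0.13 (SE; adjusted p = 0.011), from 1.37 ± 0.14 to 0.45 ± 0.18 (SD, n = 4), and the transcription factor Nfil3 fell by 0.73 ± 0.14 (adjusted p = 0.04). Dkk2, a Wnt pathway antagonist, fell by 1.19, and Ak5, Emid1, Scml4, Aox1 and Hdac8 fell by 0.93, 0.91, 0.79, 0.61 and 0.58. Hpgds, a prostaglandin D synthase, rose by 0.96 ± 0.15 (adjusted p = 0.025). With each of the 8 arrays left out in turn, Arntl still passed. Emid1 did not in 2 of the 8 cases, Dkk2 and Hpgds did not in 5, Scml4 and Hdac8 did not in 6, and Nfil3, Ak5 and Aox1 did not in all 8. The share of higher genes was 22.2%, and 40.9% with quantile normalization and 34.8% with normexp before it. Cxcl5 at 2.83 (adjusted p = 0.083), Mapk7 at 0.34, Ppan at 0.45, Krt9 at 0.87 and Mrto4 at 0.35 did not pass. Ins1, Ins2, Gcg, Sst and Ppy differed by -0.03, -0.08, -0.10, -0.05 and -0.50, and Mki67 by 0.29, none past the threshold. The groups lie on different slides, and limma called 0 genes both with only these 8 arrays in the fit (2030 at an unadjusted p under 0.05) and with the acinar score as a covariate (1666). With the lymphocyte score as a covariate the count was 33.

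In BLKS islets on high-fat diet, 5 lists passed with camera's preset correlation, and none with an estimated correlation (adjusted p = 0.98 for each). Beta-cell identity genes had a median of -0.13 over 33 members (camera adjusted p = 0.0036), with the transcription factor Nkx6-1 at -0.38, Ffar1 at -0.57, Ucn3 at -0.29 and the glucose transporter Slc2a2 at -0.28. This call rests on high-fat mouse 3, without which the median was -0.04 and did not pass, and the array score gave an exact permutation p of 0.171. Without the arrays of high lymphocyte score, of which this is 1, the list gave adjusted p = 0.34 (in a range from 0.001 to 0.98 over alternatives). Genes of the unfolded protein response had a median of -0.13 over 40 members (adjusted p = 0.001), with Herpud1 at -0.37, Ddit3 at -0.49 and Sdf2l1 at -0.38 (median -0.08 without chow mouse 1, still past the threshold). Cholesterol synthesis genes had a median of 0.17 over 23 members (adjusted p = 9.8e-05), with Acat2 at 0.39, Dhcr7 at 0.37 and Nsdhl at 0.30, and 1 rose adjusted over the list alone. Their median was 0.07 without chow mouse 2 and 0.05 and 0.26 without high-fat mouse 1 and 3, each past the threshold. Inflammation genes had a median of 0.27 (adjusted p = 0.013), with Il6 at 1.02 and Ccl2 at 1.62, and 1 rose adjusted over the list alone. They did not pass without chow mouse 3 (0.23) or high-fat mouse 3 (0.12), and the median was 0.11 without high-fat mouse 2. No member of these lists passed over all genes. Exact permutation p of the array scores was 0.286 for cholesterol synthesis and 0.114 for inflammation. For the unfolded protein response it was 0.0286 (0.05 adjusted over contrasts). Acinar markers had a median of 2.60 (adjusted p = 5.3e-10), with Cela2a at 3.93 and Cpb1 at 3.73, and their array score differed by 2.57 (exact permutation p = 0.257), with a median of 0.73 without chow mouse 1.

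For pioglitazone added to the high-fat diet in BL6 islets, 44 genes passed, 23 higher and 21 lower. Chance cannot be excluded for this count, as 2 of 35 splits of the arrays called as many and 1 of them 161. A few of the called names share a locus with another, on chromosomes 1 and 7, so the count is of names rather than loci. Cd36, a fatty acid transporter (mm9 chromosome 5, 17288600 to 17288659), rose by 2.45 ± 0.31 (SE; 5.47-fold, adjusted p = 8e-04), from -2.45 ± 0.52 to 0.00 ± 0.27 (SD, n = 4). Fabp4, a fatty acid binding protein and known PPAR-gamma target, rose by 1.96 ± 0.23 (3.89-fold, adjusted p = 0.00029), and Rbp7, a retinol binding protein, by 1.40 ± 0.19 (2.65-fold, adjusted p = 0.0015). Lrtm2, Edn2, Ankrd34c and Abcc3 rose by 1.23, 1.34, 1.39 and 1.03, and the dim Olfr1312 rose by at least 1.11-fold. The activity-regulated Npas4 fell by 1.79 ± 0.29 (adjusted p = 0.0087), and Vgf, a neuroendocrine peptide precursor, fell by 1.09. For Npas4, handling of the islets before lysis cannot be told apart from pioglitazone, as no isolation batch is given. Tnfrsf11b, Wfdc1, Six4, Kcnab3, Ccdc117 and Pcp4 fell by 1.11, 0.92, 0.85, 0.76, 0.72 and 0.70. With each of the 8 arrays left out in turn, Cd36, Fabp4, Rbp7, Lrtm2, Npas4 and A030001D16Rik still passed, and each other gene named here as changed did not in 1 (Wfdc1) to 7 (Tnfrsf11b) of the 8 cases. The share of higher genes was 52.3%, from 38.1% with the authors' value table to 64.7% without the arrays of high lymphocyte score. A030001D16Rik, outside the naming rule, was at least 12.6-fold lower. Ins1, Ins2, Gcg, Sst and Ppy differed by -0.03, -0.09, 0.04, 0.10 and -0.36, and Pparg itself by -0.12, none past the threshold. The groups lie on different slides, and with only these 8 arrays in the fit limma called 0 genes (1170 at an unadjusted p under 0.05). Without the arrays of high lymphocyte score the count was 17, and Npas4 stood at -1.22 (adjusted p = 0.21, in a range from 0.0044 to 0.69 over alternatives). That setting removed high-fat mouse 4 and pioglitazone mice 2 and 3, so the lower count may reflect fewer arrays.

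Among the lists, 2 of 44 PPAR target genes rose with pioglitazone in BL6 islets, and the list as a whole did not pass (median 0.03, adjusted p = 0.11). Genes of the unfolded protein response had a median of -0.22 over 40 members (camera adjusted p = 2.2e-08, and adjusted p = 0.62 with an estimated correlation), with Sec23b at -0.46, Dnajb9 at -0.50 and Manf at -0.34. Cholesterol synthesis genes had a median of -0.14 (adjusted p = 0.0074, and adjusted p = 0.87 with an estimated correlation), with Cyp51 at -0.54 and Lss at -0.43, and 2 fell adjusted over the list alone. They did not pass without high-fat mouse 1 (-0.11), and the median was -0.09 without pioglitazone mouse 3. Secretory granule and exocytosis genes had a median of -0.11 (adjusted p = 0.0074, and adjusted p = 0.89 with an estimated correlation), where Vgf fell, Unc13a stood at -0.48 and 2 fell adjusted over the list alone. They did not pass without high-fat mouse 2 (-0.09) or pioglitazone mouse 3 (0.01), and the median was -0.23 and -0.18 without pioglitazone mouse 1 and 4. Alpha-cell markers had a median of 0.72 over 8 members (adjusted p = 0.0049, and adjusted p = 0.82 with an estimated correlation), with the transcription factors Irx2 at 0.91 and Irx1 at 0.95, and 5 rose and 1 fell adjusted over the list alone, but the list did not pass without high-fat mouse 1 (0.49). Macrophage markers had a median of 0.43 (adjusted p = 0.0016, and adjusted p = 0.82 with an estimated correlation), which rests on pioglitazone mouse 3, at a score of 2.30 where the others lay from 0.25 to 0.78. Without this mouse the median was -0.06 and did not pass. Apoptosis genes had a median of 0.21 (adjusted p = 0.0081, and adjusted p = 0.48 with an estimated correlation) and did not pass without high-fat mouse 1 (0.17) or pioglitazone mouse 3 (-0.02), with 0.12 without high-fat mouse 3. Exact permutation p of the array scores was 0.0857 for the unfolded protein response, 0.143 for cholesterol synthesis and 0.343 for exocytosis genes. It was 0.0571 for alpha-cell markers, 0.4 for macrophage markers and 0.171 for apoptosis genes. The lymphocyte score was 0.96 higher in these islets (exact permutation p = 0.514). The exocytosis, macrophage and apoptosis lists also did not pass without the arrays of high lymphocyte score (adjusted p = 0.35, 0.65 and 0.68, in ranges from 0.005 to 0.89, from 6.8e-05 to 0.82 and from 0.00044 to 0.68 over alternatives). Fewer arrays were left there, so these losses cannot be put down to lymphoid tissue alone.

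In BLKS islets, 1 gene passed for pioglitazone added to the high-fat diet, and chance cannot be excluded for this count (7 of 35 splits called as many). Rbp7 rose by 1.48 ± 0.19 (SE; 2.79-fold, adjusted p = 0.0036), from 0.01 ± 0.17 to 1.5 ± 0.09 (SD, n = 4), and passed with each of the 8 arrays left out in turn. Fabp4 and Cd36, looked up here because they rose in BL6 islets, stood at 1.09 ± 0.23 (adjusted p = 0.089) and 0.86 ± 0.31 (adjusted p = 0.83). Several large differences did not pass, with Stac at 2.56 and Scn2b at 2.33 (adjusted p = 0.051 for each), Rit2 at 1.16 and Nsg2 at 3.74 (adjusted p = 0.061), and Tmeff2 at least 2.99-fold higher (adjusted p = 0.051). Ssh1, Ttll3, Diexf, Utp20 and Dkc1 stood at -0.45, -0.43, -0.32, -0.37 and -0.31, far from the threshold. Ins1, Ins2, Gcg, Sst and Ppy differed by -0.09, -0.03, -0.01, 0.04 and 0.37. Both groups lie on slide 3, and the count was 52 without BLKS pioglitazone mouse 4.

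**Figure D1:**
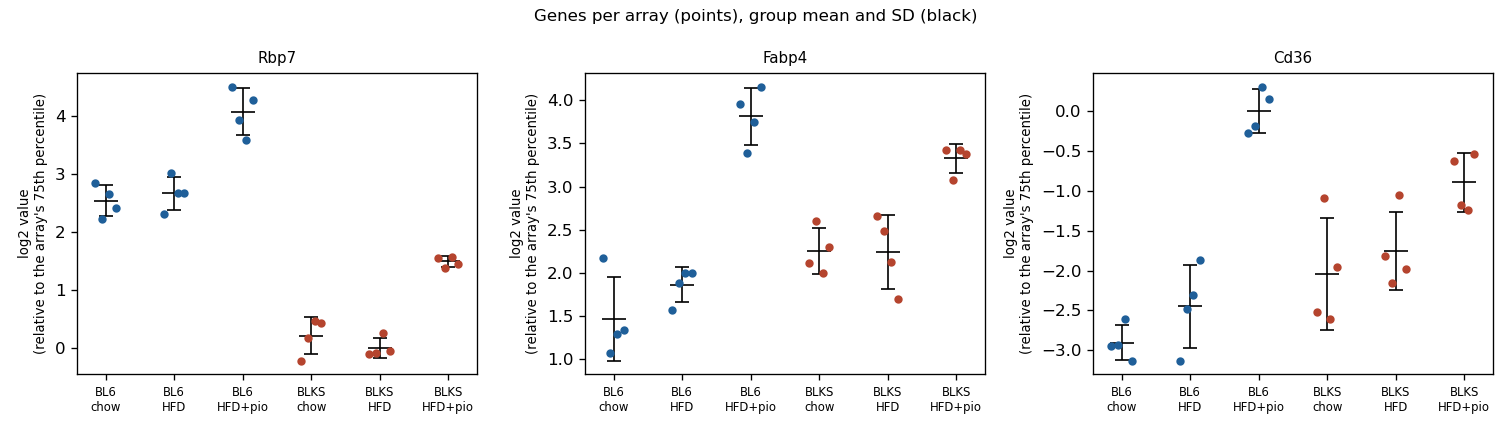
Log2 value of Rbp7, Fabp4 and Cd36 relative to the array's 75th percentile, by strain and diet, with 1 point per array and the group mean and SD in black. Rbp7 rose with pioglitazone by 1.40 in BL6 and by 1.48 in BLKS islets, and lay 2.32 lower in BLKS than in BL6 islets on chow.

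Schwann-cell and neural markers were higher with pioglitazone in BLKS islets, with a median of 0.57 over 8 members (camera adjusted p = 1.6e-05, and adjusted p = 0.22 with an estimated correlation). Of these, 3 rose adjusted over the list alone and none over all genes. The glial gene Gfap was at least 3.71-fold higher (adjusted p = 0.099), with S100b at 1.69 and Ngfr at 1.35. Interferon response genes had a median of 0.31 over 29 members (adjusted p = 9.5e-05, and adjusted p = 0.86 with an estimated correlation), with Ifit2 at 0.74 and Irgm1 at 0.27 (median 0.20 without high-fat mouse 2, still past the threshold). Cholesterol synthesis genes had a median of -0.13 (adjusted p = 1.9e-05, and adjusted p = 0.86 with an estimated correlation), with Lss at -0.31 and Srebf2, a regulator of the pathway, at -0.51. They did not pass without high-fat mouse 1 (-0.07), and the median was -0.23 without high-fat mouse 3. Cell cycle genes had a median of -0.36 (adjusted p = 0.0026, and adjusted p = 0.96 with an estimated correlation), but no direction is given for them, as the median turned to 0.13 without high-fat mouse 3 and did not pass. Nor did it pass without pioglitazone mouse 3 (-0.21), it was -0.59, -0.54 and -0.64 without high-fat mouse 1, high-fat mouse 2 and pioglitazone mouse 1, and the array score gave an exact permutation p of 0.571. Exact permutation p of the array scores was 0.0571 for Schwann-cell and neural markers, 0.0571 for interferon response and 0.286 for cholesterol synthesis genes. The PPAR target list had a median of 0.06 and did not pass (adjusted p = 0.10).

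On chow, 9545 of 22968 genes (41.6%) differed between the strains, 4727 higher and 4818 lower in BLKS (49.5% higher, and from 43.3% to 50.9% over other settings). Atf3, a stress-induced transcription factor (mm9 chromosome 1, 192994547 to 192994606), was 8.02 ± 0.52 (SE) higher on the log2 scale in BLKS than in BL6 islets (adjusted p = 1.6e-10), at 4.90 ± 0.45 against -3.12 ± 0.30 (SD, n = 4). The immediate early gene Fosb was 6.49 ± 0.23 higher (adjusted p = 1.8e-14), and the cytokine gene Il6 was at least 25.6-fold higher. Cxcl1, Apol8, Serpina3i and Fam71a were at least 13.5-fold, 14.6-fold, 14.4-fold and 21.4-fold higher. H2-Ea-ps, in the major histocompatibility complex, was at least 25.9-fold higher, and H2-Q1 in the same complex at least 91.6-fold lower (mm9 chromosome 17, 35461859 to 35461918). Tmc7 and Olfm3 were at least 22.7-fold and 8.20-fold lower. Afm, Fggy, Caps2, Rnf150 and Sucnr1 were lower in BLKS islets, with log2 differences of -5.58, -4.53, -4.51, -4.08 and -3.97. Ins1, Ins2, Gcg, Sst, Ppy, Pdx1 and Slc2a2 differed by between -0.15 and 0.13 without passing, Mafa was lower (-0.30, adjusted p = 0.036, not past the threshold in 6 of 8 cases of 1 array left out) and Pparg higher (0.64, adjusted p = 0.002). The 2 groups lie on different slides.

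By group, 21 of 22 immediate early genes were higher in BLKS islets on chow and none lower, with a median of 3.40 (camera adjusted p = 5.2e-20, and adjusted p = 0.009 with an estimated correlation). Jund was higher by 3.37, Ier3 by 3.68 and Klf4 by 2.97. Of 26 inflammation genes 17 were higher and none lower (median 2.57, adjusted p = 2.2e-07, and adjusted p = 0.20 with an estimated correlation), among them the feedback inhibitors Socs3 at 3.40 and Nfkbia at 2.51, and Cxcl2 at least 16.2-fold. Genes of the unfolded protein response had 21 members higher and 3 lower (median 0.39, adjusted p = 2.2e-05, and adjusted p = 0.72 with an estimated correlation), with Ppp1r15a at 3.41, Trib3 at 2.82 and Ddit3 at 2.33. Cholesterol synthesis had 13 higher and 1 lower (median 0.66, adjusted p = 0.00056, and adjusted p = 0.77 with an estimated correlation), with Fdft1 at 1.26 and Fdps at 1.21. Ductal-cell markers had 7 higher and none lower (median 0.80, adjusted p = 0.038, and adjusted p = 0.72 with an estimated correlation), with Spp1 at 2.85 and Krt19 at 3.94, but did not pass without BL6 mouse 1 or 3 or BLKS mouse 2 (medians from 0.57 to 1.35 over the arrays left out in turn). Adjusted over the list alone, the counts of higher and lower members were 21 and 0 for immediate early genes, 18 and 0 for inflammation, 21 and 3 for the unfolded protein response, 14 and 2 for cholesterol synthesis and 8 and 0 for ductal markers. No isolation batch is given, so for all these lists handling of the islets before lysis cannot be told apart from strain. Lists that did not pass as a whole still held called members, as 41.6% of all genes were called here. Counts of called members alone are therefore not read as a result about these lists. Of 33 beta-cell identity genes 6 were higher and 11 lower (adjusted p = 0.32 for the list), with Npas4 higher by 4.55 and Rfx6, Foxa2 and Glp1r lower (-1.56, -1.36 and -1.23). Of 32 antioxidant genes 11 were higher and 8 lower (adjusted p = 0.32), with Hmox1 and Mt2 higher by 3.30 and 2.07 and Gpx2 lower (-1.40). Of 24 glycolysis genes 7 were higher and 1 lower (adjusted p = 0.32), with the glucose transporter Slc2a1 higher by 1.64. Of 26 cell cycle regulators 7 were higher and 4 lower (adjusted p = 0.85), with the inhibitor Cdkn1a higher by 2.61 and Ccnd1 lower (-0.87). Of 44 PPAR targets 9 were higher and 12 lower (adjusted p = 0.99), with Cidea at 3.01 and Pdk4 at -2.21.

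**Figure D2:**
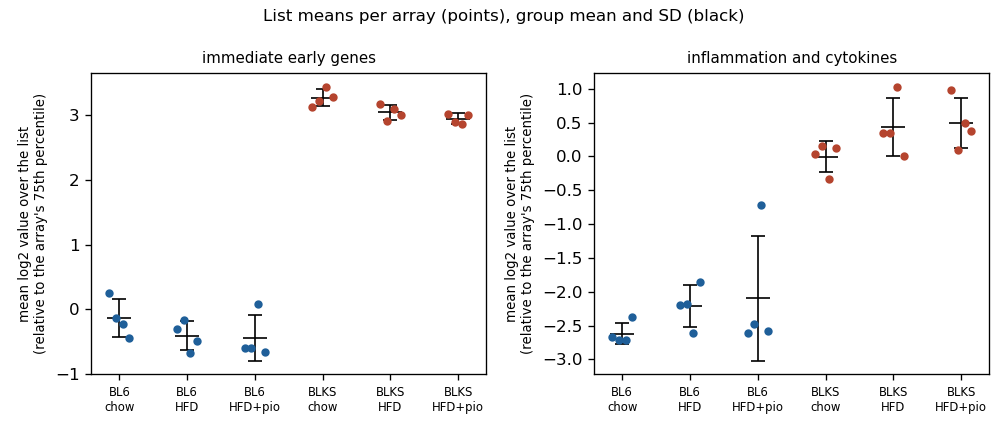
Mean log2 value of the immediate early genes and of the inflammation genes on each array, relative to the array's 75th percentile, with 1 point per array and the group mean and SD in black. The immediate early score was -0.13 in BL6 and 3.27 in BLKS islets on chow, and all 12 BLKS arrays lay above all 12 BL6 arrays.

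On high-fat diet, Atf3 was 7.63 ± 0.52 (SE) higher in BLKS than in BL6 islets and Il6 at least 44.4-fold higher, with Cxcl1, Egr4 and Cxcl2 at least 37.3-fold, 16.1-fold and 18.7-fold higher. The acinar protease gene Ctrc was higher by 6.09 ± 1.56 (adjusted p = 0.0029). H2-Q1, Afm and Tmc7 were at least 80.2-fold, 29.9-fold and 24.5-fold lower, and the neuropeptide gene Vip stood at -4.91 (adjusted p = 0.0051). In all, 11466 genes passed (49.9% of those tested), 5347 higher and 6119 lower (46.6% higher, and from 44% to 52.4%, the latter with the authors' value table). Immediate early genes (21 higher, none lower, median 3.29, camera adjusted p = 6.9e-18, and adjusted p = 0.016 with an estimated correlation), inflammation (17 higher, 1 lower, median 2.22, adjusted p = 1.6e-06, and adjusted p = 0.28 with an estimated correlation), cholesterol synthesis (14 higher, none lower, median 0.67, adjusted p = 6.4e-05, and adjusted p = 0.81 with an estimated correlation) and the unfolded protein response (18 higher, 3 lower, median 0.28, adjusted p = 0.0045, and adjusted p = 0.96 with an estimated correlation) were higher. Of 45 oxidative phosphorylation genes, 17 were lower and none higher (median -0.20, adjusted p = 0.044, and adjusted p = 0.96 with an estimated correlation), but the list did not pass without BL6 mouse 1 or 2 or BLKS mouse 3 or 4 (medians from -0.25 to -0.16). Adjusted over the list alone, 16 cholesterol synthesis genes were higher and 14 oxidative phosphorylation genes lower, and the counts of the other 3 lists were as over all genes. Slc2a2 was lower in BLKS (-0.40, adjusted p = 0.016, and not past the threshold without BL6 mouse 2 at -0.35 or BLKS mouse 3 at -0.33) and Pparg higher (0.98, adjusted p = 2.1e-05). The groups lie on different slides. Between the BLKS chow and BL6 pioglitazone arrays of slide 2, none of which enter this contrast, 94.1% of the called genes had the same sign.

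On high-fat diet with pioglitazone, Atf3 was 8.15 ± 0.52 (SE) higher in BLKS islets, the heat-shock gene Hspa1a 6.65 higher and the chemokine gene Ccl2 6.01 higher, and Il6 was at least 50-fold higher. H2-Q1, Afm, Sucnr1 and Bmpr1b were at least 76.8-fold, 37.4-fold, 10.6-fold and 14.7-fold lower. Of 10520 genes past the threshold (45.8% of those tested), 5280 were higher and 5240 lower. The same 5 lists as on chow passed, with 21 immediate early genes (median 3.46, adjusted p = 2.4e-18, and adjusted p = 0.014 with an estimated correlation), 19 inflammation genes (2.27, adjusted p = 1.1e-06), 23 unfolded protein response genes (0.49, adjusted p = 2.7e-06), 17 cholesterol synthesis genes (0.66, adjusted p = 7.7e-05) and 7 ductal markers (0.90, adjusted p = 0.048) higher. With an estimated correlation the other 4 gave adjusted p = 0.26 for inflammation and 0.82 for each of the rest. Of these lists, the unfolded protein response had 2 members lower and cholesterol synthesis 1. Macrophage markers (14 of 23 lower and 1 higher, median -1.02, adjusted p = 0.0076) and red blood cell markers (6 of 7 lower, median -1.50, adjusted p = 0.044) were lower in BLKS, with adjusted p = 0.82 for each with an estimated correlation. The macrophage list did not pass without BL6 mouse 3 (-0.74), and its array score gave an exact permutation p of 0.143. The red blood cell list did not pass without BL6 mouse 2 or 3 or BLKS mouse 3 or 4 (medians from -1.84 to -1.22), nor the ductal list without BL6 mouse 1, 3 or 4 or BLKS mouse 3 or 4 (medians from 0.74 to 1.20). Adjusted over the list alone, 20 inflammation genes were higher and 16 macrophage markers lower, and the other counts were as over all genes. The share of higher genes was 50.2%, from 42.8% without the arrays of high lymphocyte score to 61.8% with the authors' value table, and the groups lie on different slides. Over the 3 diets, which share no arrays, 3670 genes were higher in BLKS on each and 3455 lower, where 253 and 293 would be shared by independent lists of these sizes.

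The test of whether the strains responded differently to high-fat diet called 0 genes with limma, and 1938 had an unadjusted p under 0.05. Akap8 at 0.64 and Cdkn2c at -0.86 had the smallest p (adjusted p = 0.079 for each), followed by NEAT2 at 1.71 and P2ry1 at -1.47. Macrophage markers (median -0.53, camera adjusted p = 0.0057), cell cycle genes (-0.56, adjusted p = 0.031) and cell cycle regulators (-0.15, adjusted p = 0.048, with Cdkn1a at -0.91 and Cdkn2a at -1.11) had lower changes in BLKS than in BL6 islets. So did unfolded protein response (-0.12) and oxidative phosphorylation genes (-0.09), with adjusted p = 0.031 for each. All 5 gave adjusted p = 0.96 with an estimated correlation. Their calls also ended in 1, 4, 8, 5 and 4 of 12 other settings, in this order. Of 16 arrays left out in turn, 1 ended the call of macrophage markers (BL6 high-fat mouse 4, median -0.45, with -0.31 without BLKS chow mouse 2), and 9, 11, 6 and 7 ended those of the other lists in this order, with medians from -0.99 to -0.34, -0.20 to -0.06, -0.18 to -0.06 and -0.15 to -0.06. No member passed over all genes, while 3 cell cycle regulators were lower adjusted over the list alone. For pioglitazone, 2 genes passed, a count that 6 of 100 splits reached, so chance cannot be excluded. Lrtm2 had a lower change in BLKS islets (-1.19 ± 0.19, adjusted p = 0.036), and A030001D16Rik, outside the naming rule, had a higher one (4.38 ± 0.66, adjusted p = 0.036), a fitted value from a gene not well above background in BL6 islets with pioglitazone. With each of 16 arrays left out in turn, Lrtm2 did not pass in 8 cases and A030001D16Rik did not in 7. Slc25a32 at 0.79 (adjusted p = 0.052), Stac at 3.35 and Wfdc1 at 1.24 did not pass, nor did Rbp7 at 0.08, Fabp4 at -0.87 and Cd36 at -1.59. These contrasts cross slides, and limma called 0 genes for pioglitazone without the arrays of high lymphocyte score (2430 at an unadjusted p under 0.05).

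Acinar-cell markers differed widely between arrays of a group. Their score was 2.29 ± 3.11 (SD, n = 4) in BL6 and 2.03 ± 3.88 in BLKS islets on chow, and 4.00 ± 1.39 and 4.61 ± 1.35 on high-fat diet. With pioglitazone the scores were 4.33 ± 0.55 in BL6 and 4.68 ± 2.38 in BLKS islets. None of 7 contrasts of 2 groups passed an exact two-sided permutation test, with p from 0.257 to 1 and a Benjamini-Hochberg adjusted p of 1 for each. Reg family genes, expressed in acinar cells and regenerating islets, had medians of 1.57 on high-fat diet in both strains without passing (camera adjusted p = 0.12 in BL6 and 0.32 in BLKS).

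**Figure D3:**
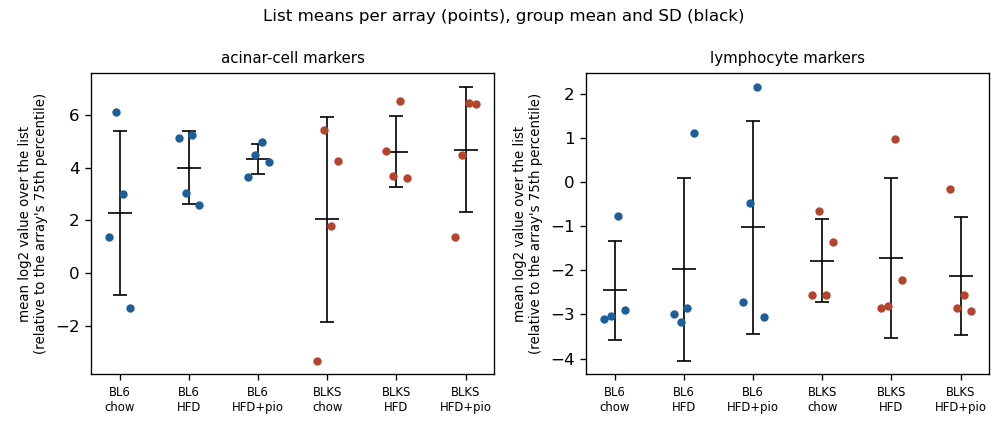
Mean log2 value of acinar-cell and of lymphocyte markers on each array, relative to the array's 75th percentile, with 1 point per array and the group mean and SD in black. The acinar score ranged from -3.32 to 6.51, and 1 array of BL6 islets with pioglitazone had a lymphocyte score of 2.16.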

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

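The slide tests of immediate early and of cell cycle genes, the test of islet handling, the direction held against probe variants in immediate early genes and the lymphocyte score as a covariate were chosen only after results had been seen.

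Immediate early genes were higher in BLKS islets on all diets. A difference between slides is argued against by the median of 3.40 over 22 members within slide 2, where 20 members were separated between 3 BLKS chow and 3 BL6 pioglitazone arrays. Variants under probes designed on the BL6-based reference would lower the BLKS signal, yet 21 of 22 genes were higher and none lower on each diet, and the 2 other probes of these genes that passed the filter had a median of 1.67. All 12 BLKS arrays had scores above all BL6 arrays, and no isolation batch is given, so handling of the islets before lysis cannot be told apart from strain. The same limit holds for the other strain differences, among them those of inflammation and unfolded protein response genes. It holds too for differences of Egr1, Fos and Npas4 on high-fat diet or with pioglitazone. A difference in stress signalling between strains stays open as a hypothesis.

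Cell cycle genes were higher on high-fat diet in BL6 islets. Lymphoid tissue in some samples would bring dividing cells, yet the median was 0.54 with the lymphocyte score as a covariate (camera adjusted p = 4e-12), against 0.68 without it. Both groups lie on slide 1, so the median of 0.68 cannot come from a difference between slides, though chow and high-fat arrays lie in different rows of it. The diet stays open, and the list's call is lost with an estimated correlation (adjusted p = 0.73).

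Of genes at least 4-fold lower in BLKS islets on all diets, there were 171. Sequence variants under the probes would spare other probes of the gene, yet 91.8% of 73 such probes were at least 2-fold lower, against 83.9% of 118 at least 2-fold higher among genes 4-fold higher (two-sided Fisher's exact p = 0.13). These probes cover at most 73 of the 171 genes. The rest had no other passing probe and were not tested for variants. Within slide 2, whose arrays had a part in choosing the genes, 100% were at least 2-fold lower. Expression differences between the strains are a hypothesis that the data leave open, and a variant spanning all probes of a gene was not tested.

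Single arrays stood apart from the other 3 of their group in 16 of 168 list scores, where chance gives about 1 in 20. Lymphocyte markers stood at -0.78 in BL6 chow mouse 3, 1.12 in BL6 high-fat mouse 4, 0.97 in BLKS high-fat mouse 3 and -0.15 in BLKS pioglitazone mouse 1, with the others of each group at or below -2.22. Macrophage markers stood at 1.03 in BL6 high-fat mouse 4. BL6 pioglitazone mouse 3 stood apart in cell cycle genes (0.76), inflammation (-0.72), immediate early genes (0.08) and apoptosis (0.48). BLKS high-fat mouse 3 stood apart in exocytosis genes (3.78), the unfolded protein response (4.56) and dedifferentiation genes (0.25). BL6 chow mouse 1 stood apart in endothelial (1.47) and neural markers (-0.98), BL6 chow mouse 4 in inflammation (-2.38) and BLKS chow mouse 2 in cholesterol synthesis (1.92).

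A test of the strain difference in response passed in these cases with all arrays, though leaving out 1 array ended the call of most lists. For high-fat diet, medians were -0.53 for macrophage markers, -0.56 for cell cycle genes, -0.15 for cell cycle regulators, -0.12 for the unfolded protein response and -0.09 for oxidative phosphorylation, and 1, 9, 11, 6 and 7 of the 16 arrays left out in turn ended these calls in this order (the 1 being BL6 high-fat mouse 4, with a median of -0.45). For pioglitazone, A030001D16Rik stood at 4.38, a fitted value that is no exact difference because the gene was well above background on 0 of 4 BL6 pioglitazone arrays, and Lrtm2 at -1.19, and chance is not excluded for these 2 genes (6 of 100 splits). Medians were -0.57 for alpha-cell markers (adjusted p = 0.012), -0.45 for macrophage markers (0.044), -1.06 for lymphocyte markers (0.049), 1.22 for Schwann-cell and neural markers (0.00063) and 0.19 for the unfolded protein response (0.00017). The last 2 passed with each array left out. The alpha-cell call ended without BL6 high-fat mouse 1 (-0.46), and those of macrophage and lymphocyte markers ended without 8 and 10 of the 16 arrays, with medians of -0.03 and -0.21 without BL6 pioglitazone mouse 3 and -2.10 for lymphocyte markers without BL6 high-fat mouse 4. With an estimated correlation none of these lists passed, with adjusted p from 0.70 to 0.96. Of 12 other settings, 5 and 7 ended the macrophage and lymphocyte calls for pioglitazone. For high-fat diet, 1, 4, 8, 5 and 4 did, in the order above.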

How the results depend on the processing

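Strain counts stayed within 1.5 times under all alternatives run, while diet and pioglitazone counts did not, and the causes were not tested. The groups compared between the strains lie on different slides, so no alternative could remove a slide difference from the strain counts. Slide as a fixed block was run only for BL6 high-fat diet and BLKS pioglitazone. As a random block its correlation within a slide was -0.012. Leaving out arrays of high lymphocyte score, that score as a covariate and leaving out each mouse for gene lists were chosen only after the data were seen. No named gene that was called changed sign, and genes called in neither fit (68 and 13 changes of sign, and 108 with a mouse left out) were given no direction. In order, counts are for high-fat diet in BL6 (10) and BLKS (18), pioglitazone in BL6 (44) and BLKS (1), and the strain difference in response to high-fat diet (0) and pioglitazone (2). Normexp with quantile normalization gave 66 for BLKS high-fat diet and 11 for the high-fat difference. Quantile normalization gave 16 for BL6 high-fat diet, 68 for BL6 pioglitazone and 2 for the high-fat difference. No filter gave 6, 6, 23 and 3 for the 4 diet contrasts and 0 for the pioglitazone difference. Probes well above background on all arrays gave 1 for the pioglitazone difference. The value table gave 16, 5, 21, 4 and, for the pioglitazone difference, 1. Only the groups compared, with fewer samples, gave 0, 0 and 0 for the first 3 and 4 for the high-fat difference. The acinar score as a covariate gave 6, 0, 6 for BLKS pioglitazone and 1 for the pioglitazone difference. Leaving out 5 arrays of high lymphocyte score gave 5 for BL6 high-fat diet, 17 for BL6 pioglitazone and 0 for the pioglitazone difference, and that score as a covariate gave 33 for BLKS high-fat diet and turned the lymphocyte list's pioglitazone difference upward (adjusted p = 0.96, in a range from 0.0064 to 0.96). Slide as a fixed block gave 13 for BL6 high-fat diet and 1 for BLKS pioglitazone.

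The replicate block gave 8 for BLKS high-fat diet, 23 for BLKS pioglitazone, 4 for the high-fat difference and 10 for the pioglitazone difference. Same-numbered mice did not deviate together (mean r = 0.006 over 60 pairs, against 0.009 over 180 others), so the numbers pair no samples. Leaving out each mouse in turn gave 4 to 18 genes for BL6 high-fat diet (6 and 4 without chow mice 2 and 3, 18 and 5 without high-fat mice 1 and 4) and 2 to 14 for BLKS high-fat diet (4, 5, 2 and 11 without chow mice 1 to 4, and 5, 6 and 2 without high-fat mice 1 to 3). It gave 18 (without high-fat mouse 2) to 63 for BL6 pioglitazone, 1 to 52 for BLKS pioglitazone (52 without pioglitazone mouse 4), 0 to 1 for the high-fat difference (1 without BLKS chow mouse 4) and 0 to 22 for the pioglitazone difference. The last was 0 without BL6 high-fat mouse 1 or 2, BL6 pioglitazone mouse 2, BLKS high-fat mouse 1, 3 or 4 or BLKS pioglitazone mouse 3. It was 4 without BL6 high-fat mouse 4, 6 without BL6 pioglitazone mouse 1 or 4 or BLKS high-fat mouse 2, and 22 without BLKS pioglitazone mouse 4. Of 49 list calls, 3 passed with an estimated inter-gene correlation, and 27 were ended by at least 1 mouse left out. Adjusted p then ran from 1.8e-06 to 0.83 for macrophage markers with BL6 pioglitazone, from 0.0011 to 0.71 for their pioglitazone difference and from 5.3e-05 to 0.97 for that of lymphocyte markers, each with the direction of the test turned without BL6 pioglitazone mouse 3, and from 1.8e-06 to 0.24 for cell cycle genes with BLKS pioglitazone, turned without BLKS high-fat mouse 3. The dim Nnt probe that starts at 120142585 differed by itself by 0.29 without passing. Dim probes limit the bounds given as "at least".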

Other observations

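The lookup of clock genes and the comparison of shared calls were chosen only after results had been seen. Clock genes were looked up because Arntl and Nfil3 had been called. In BLKS islets on chow, Nr1d1 was 5.38 ± 0.32 (SE) higher than in BL6 islets (adjusted p = 3.4e-11), Dbp 2.48 (adjusted p = 1.4e-06), Nfil3 2.50, Per2 1.07 and Per1 0.92 higher, while Arntl stood at 0.27 (adjusted p = 0.095) and Clock at -0.20 (adjusted p = 0.28). No time of day or date of islet isolation is given. Collection time therefore cannot be told apart from strain or diet for these genes. On high-fat diet in BL6 islets Arntl stood at -0.45 and Nfil3 at -0.52, neither past the threshold, and the strain difference in the response of Arntl was -0.47 (adjusted p = 0.44).

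In BL6 islets, 4 genes called on high-fat diet were called in the opposite direction with pioglitazone, and these contrasts share the high-fat arrays. Of these, Lrtm2 and Cpm differed between pioglitazone and chow by 0.32 and -0.06 without passing (adjusted p = 0.24 and 0.83). A030001D16Rik and a transcribed region on chromosome 19 were not well above background on any pioglitazone array, so no level against chow is given. Groups simulated with no effect in either contrast gave at most 0 such genes in 100 simulations. Few genes are called at all without an effect, so this could not test the sharing. Independent lists would share 0.0097, a value that takes no account of the shared arrays. Splitting the shared arrays between the contrasts, which leaves each fewer arrays, gave 0 to 2. How many of the 4 owe their opposite calls to the shared arrays therefore stays open.

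Other divisions of the same arrays were used to ask whether chance can be excluded for each count. For high-fat diet, only the real grouping, 1 of 35 splits, called as many. It called 10 genes in BL6 islets (highest other 1) and 18 in BLKS islets (highest other 2). So it was for the strains on chow (9545 genes, highest other 1), on high-fat diet (11466, highest other 766) and with pioglitazone (10520, highest other 459). This is the smallest share that 35 splits can give, and it was not adjusted over the 9 contrasts. It makes chance unlikely as the source of a count but cannot exclude it. In all of these but BL6 high-fat diet, the real grouping also separates the slides. For pioglitazone in BL6 islets (44 genes, 2 of 35), a split with high-fat mice 1 and 4 and pioglitazone mice 1 and 3 called 161. It points to a structure of the samples, as high-fat mouse 4 (1.12) and pioglitazone mouse 3 (2.16) had the highest lymphocyte scores of these arrays. Chance cannot be excluded for that count, nor for pioglitazone in BLKS islets (1 gene, 7 of 35, highest other 2). Nor can it for the strain difference in response to pioglitazone (2 genes, 6 of 100, highest other 12). For that in response to high-fat diet the count was 0, so that 100 of 100 splits had to call as many (highest other 1), and the splits say nothing about chance.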
